A study of Caenorhabditis elegans with 12 samples.

How the data were processed

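Whole-animal RNA of Caenorhabditis elegans was sequenced from wild-type N2 and pmk-1(km25) mutant day-1 adults that had been held without food for 4 h in 100 mM NaCl, the low-potassium arm, or in 100 mM KCl. The labels give 4 groups of 3 biological replicates, 12 libraries in all, and each library was taken as the unit of replication. The NaCl and KCl media differ in sodium as well as in potassium, so "higher in NaCl" below means NaCl against KCl and not low potassium alone.

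The deposited table holds 1 expected count per gene and library, and the submitters' processing notes name STAR 2.7.1a, RSEM 1.3.3, R 4.3.1 and DESeq2 1.40.2. The roles of these programs, the genome build and annotation release, and the strandedness of the libraries are not given in the sources used here. All values were whole numbers as deposited, so the rounding alternative set beforehand did not apply. Genes of identical sequence carried near-identical values, as for hsp-16.48 and hsp-16.49. By a rule of at least 60 counts over the libraries and equal values in at least 10 of them, 64 genes had such a copy. Values of copies, and of genes that overlap another gene on the opposite strand, are uncertain for the single gene. Raw reads were not used here.

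The table lists 46904 genes, of which 46817 were matched by identifier to the Ensembl release 115 annotation of WBcel235 and 19509 had a count in any library. Library totals ranged from 8931797 to 11445709. Among pairs of replicates, the chi-square per degree of freedom of genes with at least 20 counts ran from 4.88 to 69.8, where sampling of reads alone would give about 1. The fit put the biological coefficient of variation at 0.299. Counts were kept by filterByExpr (13353 genes), scaled by TMM and fitted with the edgeR 4.0.16 quasi-likelihood model in R 4.3.3, with 1 mean per group and no covariate, all 12 libraries in 1 fit. Genes were called at a Benjamini-Hochberg adjusted p under 0.05. The standard error printed after ± beside a log2 fold change is its size divided by the square root of the quasi-likelihood F statistic. Abundances are TMM-scaled CPM, given as group means. A gene with no count in any library of a group has no finite fold; where such genes entered a median of a gene list, the median is also given with them set to a floor of 3 counts over the group.

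The comparisons were NaCl against KCl in wild type, the same in pmk-1, pmk-1 against wild type in NaCl and in KCl, and the difference of the salt effects between the genotypes (interaction). Positive values mean higher in NaCl, or higher in pmk-1. The sharing of the salt response was described by correlations across genes, without a p-value. The overlap of genes higher in NaCl in wild type and lower in pmk-1 in NaCl is given as a count alone. Both comparisons use the wild-type NaCl libraries, so the product expected of independent lists does not apply, and 20 simulated draws of unchanged groups, with an overlap of 0 in each, give no value for the lists called. Fixed gene lists (39 lists, 417 entries, 11 of them unmatched) were tested with camera of limma 3.58.1 at an inter-gene correlation of 0.01, adjusted over the lists with at least 3 tested members within a comparison. The same test was also run with the correlation estimated from the data, and its adjusted p is printed beside the lists the report gives as passing, which are part of all lists that passed. Members of a list were counted over all genes tested and also after adjustment over the list alone.

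The comparisons, the test, the lists, the rule for naming genes and the first set of alternatives were fixed before the data were examined. Genes named for the size of their change had an adjusted p under 0.05, a mean of at least 5 CPM over the libraries compared and groups that did not overlap (the last not for the interaction). From these were taken the 8 largest rises and 8 largest falls among genes with a gene name and 2 each way among genes known by a sequence name (4 and 1 in the pmk-1 salt response and the genotype effect in KCl), and the text prints part of them. List members were named by smallest adjusted p. Other genes in the text are stated to have been chosen after values were seen.

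The replicate numbers were tested as pairs by correlating, across genes, the deviations of same-numbered libraries from their group means. For numbers 1, 2 and 3 the correlations were 0.629, 0.197 and 0.496 in wild type between salts, 0.744, 0.391 and 0.541 in pmk-1 between salts, 0.423, 0.226 and 0.259 between genotypes in NaCl, and 0.431, 0.072 and 0.334 between genotypes in KCl. The highest correlation with another number was -0.168 or lower for number 1 in the first 3 comparisons. For number 2 it was 0.256 in wild type and 0.520 in pmk-1 between salts, above the same-number values, and 0.217 between genotypes in NaCl. For number 3 it was 0.041, 0.410 and 0.243. Only number 1 was thus clearly paired in each of them. By the same-number values the first 3 comparisons were taken as paired and the last as not paired. A replicate block was used as an alternative and not in the reported fit.

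The alternatives set beforehand were median-of-ratios scaling, the DESeq2 1.42.0 Wald test, no filter on low counts, a stricter filter (at least 10 counts in each of 3 libraries and a mean of 5 CPM), the libraries of the compared groups alone, the replicate block, each library left out in turn, and an added limit of 1 on the absolute log2 fold change. Alternatives added after the data were seen were all groups without their first replicate, the count table without ribosomal RNA genes, and the later embryo marker score or the log2 percent of ribosomal RNA counts as a covariate. The difference of median-of-ratios from TMM scaling moved the median log2 of all genes by less than 0.1 in each comparison (the largest shift was -0.03).

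The model was tested on simulated data with changes put into 100 genes per size and comparison. It recovered 38, 34, 31 and 29 percent of 2-fold changes and 65, 60, 66 and 58 percent of 4-fold changes (wild-type salt, pmk-1 salt, genotype in NaCl, genotype in KCl), with 0 calls of the wrong sign among the changed genes and 6, 4, 3 and 2 false calls. Tables and figures were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9. No value columns were left out of the table. Genes below the filter were not tested in the reported fit.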

Results

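RNA of whole day-1 adults was compared between wild-type and pmk-1(km25) animals held for 4 h in 100 mM NaCl (low potassium) or 100 mM KCl, with n = 3 libraries in each of 4 groups. Library totals lay between 8931797 and 11445709 counts, and 13353 genes were tested.

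The pmk-1 gene itself was still counted in the mutant. Its counts were 328, 308 and 358 in wild-type KCl, 217, 326 and 441 in wild-type NaCl, 206, 242 and 206 in pmk-1 KCl and 231, 200 and 180 in pmk-1 NaCl, or 32.96, 32.3, 21.8 and 23.6 CPM on average. The gene-level count includes any part of the gene outside the deletion, whose extent is not given here. In the edgeR quasi-likelihood test with Benjamini-Hochberg adjustment, pmk-1 was lower in the mutant in KCl (log2 fold change -0.59 ± 0.18, n = 3 per group, adjusted p = 0.0326). This call was lost without any of the wild-type KCl or pmk-1 KCl libraries (edgeR adjusted p = 0.0715, 0.0516 and 0.128 without wild-type KCl 1, 2 and 3, and 0.0794, 0.0651 and 0.0838 without pmk-1 KCl 1, 2 and 3) or pmk-1 NaCl 2 (0.0575). In NaCl it did not pass (log2 -0.45 ± 0.18, edgeR adjusted p = 0.0809; 0.0208 without wild-type NaCl 1). The related kinase gene pmk-2 passed in no comparison, with genotype log2 values of -0.28 ± 0.26 in NaCl and -0.55 ± 0.26 in KCl, and pmk-3 passed in the genotype effect in NaCl alone. In the pmk-1 salt response pmk-3 stood at 0.80 ± 0.20 (edgeR adjusted p = 0.0613; 0.0269 with the replicate block).

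The strains also differed in markers of sperm and embryo content. A marker score is the mean over a list's members of log2 CPM, each member centred on its mean over the 12 libraries. The sperm marker score of a library lay between -4.08 and -0.50 in wild type and between 1.93 and 3.76 in pmk-1. The later embryo marker score lay between 0.70 and 1.49 in wild type and between -2.32 and 0.41 in pmk-1. Within each of the 4 groups the first replicate stood apart from the other 2 in the sperm score, and it had the lowest later embryo score. The first principal component, with 76.0 percent of the variance, separated the genotypes and placed the first replicates of each genotype furthest to the same side. Ribosomal RNA made up 4.28 ± 0.737 percent (SD) of counts in pmk-1 NaCl and 1.65 ± 0.961, 1.49 ± 0.887 and 1.78 ± 1.35 percent in wild-type KCl, wild-type NaCl and pmk-1 KCl.

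**Figure D1:**
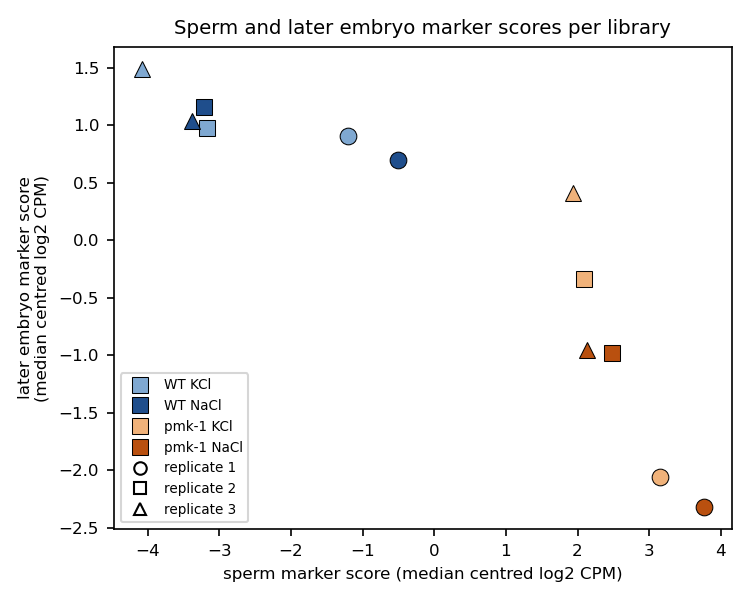
Later embryo marker score (y) against sperm marker score (x) of each library. Both are the mean over the list's members of log2 CPM centred on each gene's mean, although the axis labels say median. Colour gives the group (n = 3 each) and symbol the replicate number.

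Which genes changed between NaCl and KCl in wild-type animals? The fungus-induced-peptide-related gene fipr-22 rose from 16.9 to 136.8 CPM (log2 fold change 3.02 ± 0.35, n = 3 per group), the cytochrome P450 gene cyp-14A5 from 13.7 to 101.8 CPM (2.89 ± 0.32) and the UDP-glucuronosyltransferase gene ugt-25 from 10.6 to 64.7 CPM (2.61 ± 0.34). The zinc-finger transcription factor gene pqm-1 rose from 15.95 to 44.6 CPM (1.48 ± 0.17), the thioester-protein gene tep-1 from 86.1 to 289.3 CPM (1.75 ± 0.21), the receptor gene srr-4 from 14.5 to 71.5 CPM (2.30 ± 0.27) and dod-3, known as a gene downstream of DAF-16, from 24.4 to 109.3 CPM (2.16 ± 0.30). The phosphate transporter family gene pitr-5 (2.80 ± 0.45) and the sequence-named genes W06H8.2 (3.72 ± 0.51) and M03A1.8 (3.50 ± 0.50) rose as well. The 2 falls were the C-type lectin gene clec-1, from 134.5 to 52.5 CPM (log2 -1.36 ± 0.18), and the P450 gene cyp-29A4 (-2.54 ± 0.40). Over these named genes the edgeR quasi-likelihood test with Benjamini-Hochberg adjustment gave adjusted p from 0.00783 (fipr-22, cyp-14A5, srr-4, tep-1, pqm-1) to 0.0427 (pitr-5). In each the 3 libraries of one salt lay above the 3 of the other, which the rule for naming them required.

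In all, 23 genes rose and 2 fell in this test (edgeR), and 570 of 13353 had an unadjusted p under 0.05. With the replicate number as a block the counts were 108 and 23, and in DESeq2 105 and 27. Without the first replicates 134 genes were called, 30 of them lower. With the later embryo score as a covariate 99 rose and 20 fell, and with the ribosomal RNA covariate 12 and 1. Leaving out single libraries moved the 23 to 5, 0 and 0 (wild-type KCl 1, 2 and 3), 9, 0 and 9 (wild-type NaCl 1, 2 and 3), 40 and 13 (pmk-1 KCl 1 and 2) and 68 and 13 (pmk-1 NaCl 1 and 2). The count of 2 falls became 0 without wild-type KCl 2 or 3 or wild-type NaCl 2 or 3, 1 without wild-type KCl 1, wild-type NaCl 1, pmk-1 KCl 2 or 3 or pmk-1 NaCl 2, 8 without pmk-1 KCl 1 and 10 without pmk-1 NaCl 1.

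Epidermal antimicrobial peptide genes shifted towards NaCl as a group in wild type. None of 11 members passed over all genes tested in edgeR (8 higher at an unadjusted p under 0.05, 3 called by DESeq2, 3 with the replicate block and 6 without the first replicates), and 7 rose when adjusted over the list alone: nlp-30 (log2 3.03), cnc-2 (2.67), cnc-4 (2.17), nlp-31 (2.01), nlp-28 (0.96), nlp-27 (0.93) and nlp-33 (0.79). The list median was 0.96, with a camera Benjamini-Hochberg adjusted p = 7.24e-11 in limma and an adjusted p = 0.209 with an estimated correlation. Sodium pump and cation-chloride transport genes were placed higher by camera (26 members, limma camera adjusted p = 0.00134; adjusted p = 0.590 with an estimated correlation). Of them none passed over all genes in edgeR (5 at an unadjusted p under 0.05, 1 in DESeq2). Still, catp-1 (1.34 ± 0.27) and catp-3 (2.65 ± 0.65), both of the sodium-pump alpha-subunit family, rose when adjusted over the list alone and were called with the replicate block. Of 9 metal response genes none passed over all genes in edgeR (3 at an unadjusted p under 0.05, 0 in DESeq2) and 2 rose adjusted over the list alone (limma camera adjusted p = 3.94e-04; adjusted p = 0.369 with an estimated correlation). Neither list was particular to wild type, as limma camera also placed both higher in the pmk-1 salt response. There they did not pass with an estimated correlation (limma camera adjusted p = 0.759 for the sodium pump list and 0.638 for metal response). With the embryo covariate they did not pass either (0.667 and 0.124).

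Among 55 UDP-glucuronosyltransferase genes 1 rose, 0 fell and 54 did not pass in edgeR, with 6 up and 1 down adjusted over the list alone and 4 up with the replicate block (limma camera adjusted p = 0.00134; adjusted p = 0.590 with an estimated correlation; 0.172 without wild-type KCl 1 and 0.0698 without wild-type NaCl 3). The 10 PMK-1 immune effector genes showed no call in edgeR (0 up and 1 down at an unadjusted p under 0.05, 0 in DESeq2; list median -0.05; limma camera adjusted p = 0.467), with lys-2 at log2 -0.69 ± 0.30. The same held for the 14 genes of the p38 cascade (edgeR: 1 at an unadjusted p under 0.05, 0 in DESeq2; limma camera adjusted p = 0.201). No call over all genes tested was made among the 11 of osmotic stress (edgeR: 1 up and 1 down at an unadjusted p under 0.05, 1 in DESeq2, 1 up and 1 down adjusted over the list alone; limma camera adjusted p = 0.913). The most abundant members of the p38 cascade, osmotic and sodium pump lists stood at log2 0.03 ± 0.10 (atf-7), -0.07 ± 0.16 (wnk-1) and 0.25 ± 0.20 (eat-6).

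Sperm markers, ribosomal protein genes, body wall muscle markers and neuropeptides were also placed higher in NaCl by camera. The 53 sperm markers had a median log2 of 0.68 (0.70 with genes at 0 in a group at their bound), with 0 passing in edgeR (0 at an unadjusted p under 0.05, 0 in DESeq2) and a limma camera adjusted p = 0.00715 (adjusted p = 0.904 with an estimated correlation). The direction reversed without wild-type KCl 3 (0.659) and without wild-type NaCl 1 (4.46e-05). The list did not pass without wild-type KCl 2 (0.154) or with the embryo covariate (0.0689). The 78 ribosomal protein genes had a median of 0.19 with 0 passing in edgeR (0 at an unadjusted p under 0.05, 0 in DESeq2) and a limma camera adjusted p = 9.48e-11 (adjusted p = 0.590 with an estimated correlation), or 0.2499 without wild-type KCl 3. The 12 muscle markers had a median of 0.31, with 0 passing in edgeR (0 at an unadjusted p under 0.05, 0 in DESeq2) and a limma camera adjusted p = 0.00579 (adjusted p = 0.590 with an estimated correlation), or 0.371 without wild-type KCl 3 and 0.0627 without wild-type NaCl 1. The 50 neuropeptide genes had a median of 0.17, with 0 passing in edgeR (3 at an unadjusted p under 0.05, 0 in DESeq2) and a limma camera adjusted p = 0.00943 (adjusted p = 0.685 with an estimated correlation). They did not pass with the embryo covariate (0.0696, within 0.00773 to 0.685 over the alternatives other than single libraries), without wild-type KCl 3 (0.888) or without wild-type NaCl 2 (0.154).

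**Figure D2:**
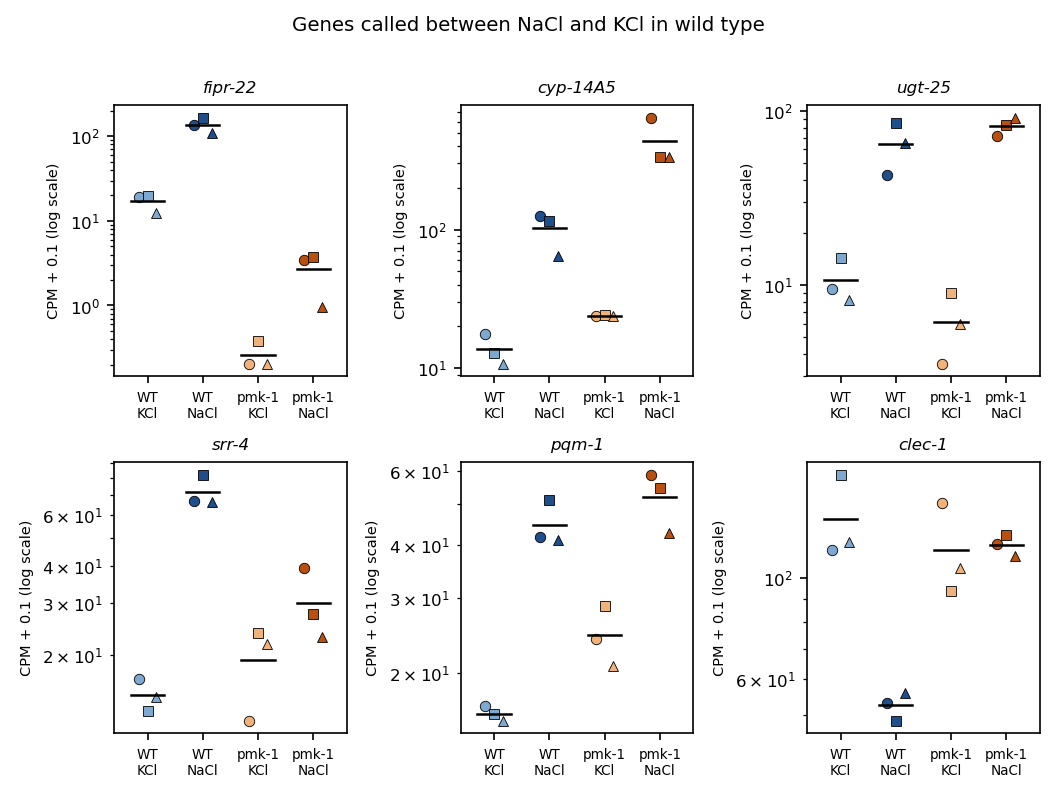
Abundance (CPM plus 0.1, log axis) of fipr-22, cyp-14A5, ugt-25, srr-4, pqm-1 and clec-1 in the 4 groups. Symbols are replicates (n = 3 libraries per group) and bars are group means.

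Which genes changed between NaCl and KCl in pmk-1 animals? The mutant raised catp-3 from 6.08 to 123.2 CPM (log2 4.34 ± 0.74, n = 3 per group), while wild type stood at 123.5 and 774.7 CPM. It was higher in 3 of 3 NaCl libraries than in any KCl library, as the rule for naming genes required. The poly(ADP-ribose) glycohydrolase gene parg-2 rose from 2.52 to 77.1 CPM (4.94 ± 0.55), and the nuclear receptor gene nhr-67 and ugt-63 by 4.78 ± 0.48 and 4.33 ± 0.58 on the log2 scale. Falls were seen in dlhd-1, of the dienelactone hydrolase family (log2 -4.40 ± 0.70), cyp-34A9 (-2.07 ± 0.39), the acyl-CoA synthetase gene acs-7 (-2.04 ± 0.26) and ZK896.5 (-2.41 ± 0.44). For these genes adjusted p in the edgeR quasi-likelihood test with Benjamini-Hochberg adjustment ran from 3.53e-04 (nhr-67) to 0.0164 (cyp-34A9). catp-3 (edgeR adjusted p = 0.00942) was not called without pmk-1 KCl 2 (0.0655), cyp-34A9 not without pmk-1 NaCl 2 (0.0811) or 3 (0.0632), and ZK896.5 not without pmk-1 KCl 3 (0.0610) or pmk-1 NaCl 2 (0.0648).

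In all, 311 genes rose and 51 fell in edgeR, 571 and 499 without the first replicates, 533 and 146 with the replicate block, and 508 and 156 in DESeq2. With the later embryo score as a covariate 387 rose and 154 fell, and with the ribosomal RNA covariate 167 and 20. The count of 311 moved to 148 and 97 without pmk-1 KCl 2 and 3 and to 188 and 159 without pmk-1 NaCl 1 and 2. The count of 51 moved to 33 and 32 without wild-type KCl 2 and wild-type NaCl 2, 132, 25 and 15 without pmk-1 KCl 1, 2 and 3, and 13 and 19 without pmk-1 NaCl 2 and 3. A fit of the 6 pmk-1 libraries alone called 43 and 5 genes and a fit of the 6 wild-type libraries alone 133 and 21, the opposite order to the joint fit, so the counts do not rank the genotypes.

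Of 55 UDP-glucuronosyltransferase genes 11 rose, 1 fell and 43 did not pass in edgeR (20 up and 2 down adjusted over the list alone; median log2 0.57). The list had a limma camera adjusted p = 1.13e-13 and an adjusted p = 0.296 with an estimated correlation. Among them were ugt-28 (2.90 ± 0.26) and ugt-29 (3.65 ± 0.34), both at an edgeR adjusted p = 2.32e-04, and ugt-25 (3.75 ± 0.36). Of 18 genes of the endoplasmic reticulum unfolded protein response 5 rose and 13 did not pass in edgeR (10 up adjusted over the list alone; median 0.40). Here camera in limma gave an adjusted p = 6.97e-08 and an adjusted p = 0.217 with an estimated correlation. The transcription factor gene xbp-1 rose from 200.5 to 400.8 CPM (1.00 ± 0.11, edgeR adjusted p = 7.77e-04), and the PERK kinase gene pek-1 (0.55 ± 0.11), the BiP chaperone gene hsp-4 (0.61 ± 0.13) and the disulfide isomerase gene pdi-2 (0.74 ± 0.16) rose as well. In edgeR pek-1 lost the call without pmk-1 KCl 2 (adjusted p = 0.0775) or 3 (0.143) or pmk-1 NaCl 1 (0.0645) or 2 (0.112). hsp-4 kept it only without wild-type KCl 1, wild-type NaCl 3 or pmk-1 NaCl 3 (edgeR adjusted p from 0.0512 to 0.180 without each of the others), and pdi-2 only without wild-type KCl 1 or 3, wild-type NaCl 1 or pmk-1 NaCl 3 (0.0531 to 0.138 without the others). Of 48 P450 genes 6 rose and 1 fell, with 41 not passing, in edgeR (7 up and 5 down adjusted over the list alone; limma camera adjusted p = 0.346), led by cyp-14A5, from 23.8 to 436.8 CPM (4.20 ± 0.33, edgeR adjusted p = 1.42e-04).

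Within the p38 cascade, 2 of 14 genes rose in edgeR and 12 did not pass (4 up adjusted over the list alone and 4 with the replicate block). For this list limma camera gave an adjusted p = 6.04e-04 and an adjusted p = 0.217 with an estimated correlation. The 2 genes were the Tribbles-like kinase gene nipi-3 (1.21 ± 0.12, edgeR adjusted p = 3.46e-04) and tir-1, the SARM-like adaptor upstream of PMK-1 (1.73 ± 0.24, 0.00337). Of 15 cytosolic heat shock genes 1 rose in edgeR, hsp-70 (3.17 ± 0.73, adjusted p = 0.0437), and 14 did not pass (6 up adjusted over the list alone; median 0.86). As a list they had a limma camera adjusted p = 3.24e-05 and an adjusted p = 0.217 with an estimated correlation. The call on hsp-70 was kept only without wild-type KCl 1, wild-type NaCl 1 or pmk-1 NaCl 3 (edgeR adjusted p from 0.0512 to 0.191 without each of the others). The PMK-1 immune effectors (0 at an unadjusted p under 0.05, 0 in DESeq2; limma camera adjusted p = 0.505) had no call in edgeR. The epidermal antimicrobial peptides had none over all genes tested (edgeR; 1 up and 1 down at an unadjusted p under 0.05, 1 in DESeq2 and with the replicate block, 1 up adjusted over the list alone, nlp-33; limma camera adjusted p = 0.676). In osmotic stress 1 of 11 fell, hmit-1.3 (log2 -1.27 ± 0.25, edgeR adjusted p = 0.0197; 0.0607 without pmk-1 KCl 3 and 0.0836 and 0.0673 without pmk-1 NaCl 2 and 3), and the list did not pass (limma camera adjusted p = 0.347).

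These groups moved beside the ribosomal RNA share, which was higher in pmk-1 NaCl than in pmk-1 KCl, and beside embryo markers. The later embryo markers had a median log2 of -1.45, with 0 of 34 passing in edgeR (3 down at an unadjusted p under 0.05, 0 in DESeq2, 8 down without the first replicates) and a limma camera adjusted p = 3.50e-04 (adjusted p = 0.759 with an estimated correlation), or 0.384 without pmk-1 KCl 3 and 0.269 without pmk-1 NaCl 1. The 78 ribosomal protein genes had a median of 0.36, with 0 passing in edgeR (30 at an unadjusted p under 0.05, 0 in DESeq2) and a limma camera adjusted p = 1.13e-13 (adjusted p = 0.662 with an estimated correlation).

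How far was the salt response shared between the genotypes? Across 13353 genes the salt log2 fold changes of wild type and pmk-1 had a Pearson correlation of 0.32 and a Spearman correlation of 0.36. They share no library, but same-numbered NaCl libraries of the genotypes deviated together, which can raise these values. At a mean of at least 5 CPM (9368 genes) these were 0.50 and 0.48. The Pearson value was 0.21 without the first replicates, and 0.23, 0.10, 0.26 and 0.23 without wild-type KCl 3, wild-type NaCl 1, pmk-1 KCl 3 and pmk-1 NaCl 1. Of the 25 genes called in wild type 23 had the same sign in pmk-1, and 14 genes rose in both. The 23 genes that rose in wild type, not the same set, had a median log2 of 2.61 there and 1.80 in pmk-1. Of the 362 called in pmk-1 326 had the same sign in wild type. The 311 genes that rose in pmk-1 had a median of 1.47 there and 0.38 in wild type. Both the genes and the sizes were read from the calls, so the median in the genotype of the call is inflated by selection.

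**Figure D3:**
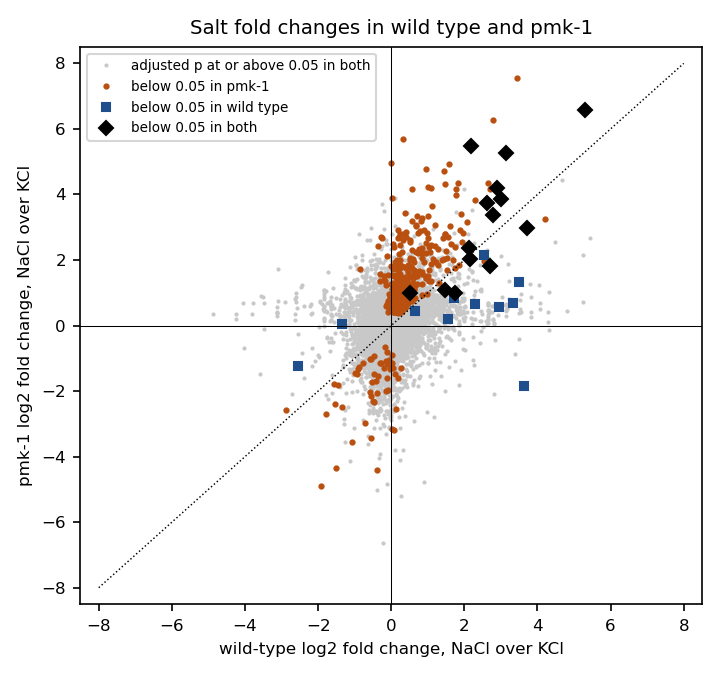
Salt log2 fold change (NaCl over KCl) in pmk-1 (y) against wild type (x) for all 13353 genes tested, n = 3 libraries per group. Colours and symbols mark genes with an edgeR adjusted p under 0.05 in wild type, in pmk-1, in both or in neither, and the dotted line marks equal change.

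Did the salt response differ between the genotypes? The acyl-CoA dehydrogenase gene acdh-2 and the asparagine synthetase gene asns-2 responded to salt in pmk-1 and differed from wild type in the direct test. In wild type acdh-2 stood at 119.8 CPM in KCl and 100.7 CPM in NaCl, and in pmk-1 at 20.8 and 133.9 CPM (difference of log2 fold changes 2.93 ± 0.28, n = 3 per group, edgeR quasi-likelihood test with Benjamini-Hochberg adjusted p = 0.00455). For asns-2 the values were 167.1 and 154.1 CPM in wild type and 49.8 and 218.9 CPM in pmk-1 (2.25 ± 0.24, edgeR adjusted p = 0.00569). Both calls held without each single library in turn (edgeR adjusted p from 0.00154 to 0.0349 for acdh-2 and from 0.00119 to 0.0456 for asns-2). acdh-2 lies at 5544778 to 5547492 of chromosome II and asns-2 at 8748434 to 8750941 of chromosome X.

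The genes Y58A7A.3 (5077854 to 5080903 of chromosome V) and Y58A7A.5 (5085704 to 5086969) were the next, at 136.7, 202.2, 44.3 and 408.9 CPM and 37.7, 80.6, 5.69 and 104.2 CPM in wild-type KCl, wild-type NaCl, pmk-1 KCl and pmk-1 NaCl. Their differences were 2.64 ± 0.35 and 3.09 ± 0.41 (edgeR adjusted p = 0.0255 for each). T27D12.1, chosen after values were seen, differed by 1.66 at the same adjusted p. In edgeR both Y58A7A genes lost the call without wild-type KCl 2 (adjusted p = 0.105) or 3 (0.168), wild-type NaCl 1 (0.105), 2 (0.107 for Y58A7A.3 and 0.0752 for Y58A7A.5) or 3 (0.133), and pmk-1 KCl 2 (0.108 and 0.107) or 3 (0.150 and 0.0979), and Y58A7A.5 also without pmk-1 NaCl 3 (0.0557).

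In all, 5 genes were more raised by NaCl in pmk-1 and 0 less raised in edgeR, with 669 of 13353 at an unadjusted p under 0.05 (439 and 230). DESeq2 called 81 and 27, the replicate block 32 and 8, and the libraries without the first replicates 58 and 39. The later embryo score as a covariate gave 47 and 13, and the ribosomal RNA covariate 3 and 0. The count of 5 became 2 without wild-type KCl 2 or 3, any wild-type NaCl library or pmk-1 KCl 3, 3 without pmk-1 KCl 2, 18 without pmk-1 KCl 1 and 12 without pmk-1 NaCl 1. The count of 0 became 2 without pmk-1 KCl 1 and 3 without pmk-1 NaCl 1.

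Among the lists, UDP-glucuronosyltransferase genes (median difference 0.47; 0 calls in edgeR over all genes, 13 up and 1 down at an unadjusted p under 0.05, 5 in DESeq2, 5 up adjusted over the list alone) had a limma camera adjusted p = 7.06e-09 and an adjusted p = 0.414 with an estimated correlation. Genes of the unfolded protein response (median 0.37; 0 calls in edgeR over all genes, 6 up at an unadjusted p under 0.05, 0 in DESeq2, 3 up adjusted over the list alone) had a limma camera adjusted p = 1.38e-06 and an adjusted p = 0.414 with an estimated correlation. Epidermal antimicrobial peptides went the other way (median -1.62; 0 calls in edgeR over all genes, 3 down at an unadjusted p under 0.05, 2 in DESeq2), with nlp-28 (-1.62) and nlp-31 (-2.76) passing when adjusted over the list alone, a limma camera adjusted p = 4.05e-04 and an adjusted p = 0.414 with an estimated correlation, or 0.115 without pmk-1 KCl 1. With the ribosomal RNA covariate the peptides did not pass (limma camera adjusted p = 0.333, within 4.81e-08 to 0.414 over the alternatives other than single libraries) and their median was -0.14. The interaction for catp-3 was 1.69 with an edgeR adjusted p = 1, so its larger fold in pmk-1 was not shown to differ.

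**Figure D4:**
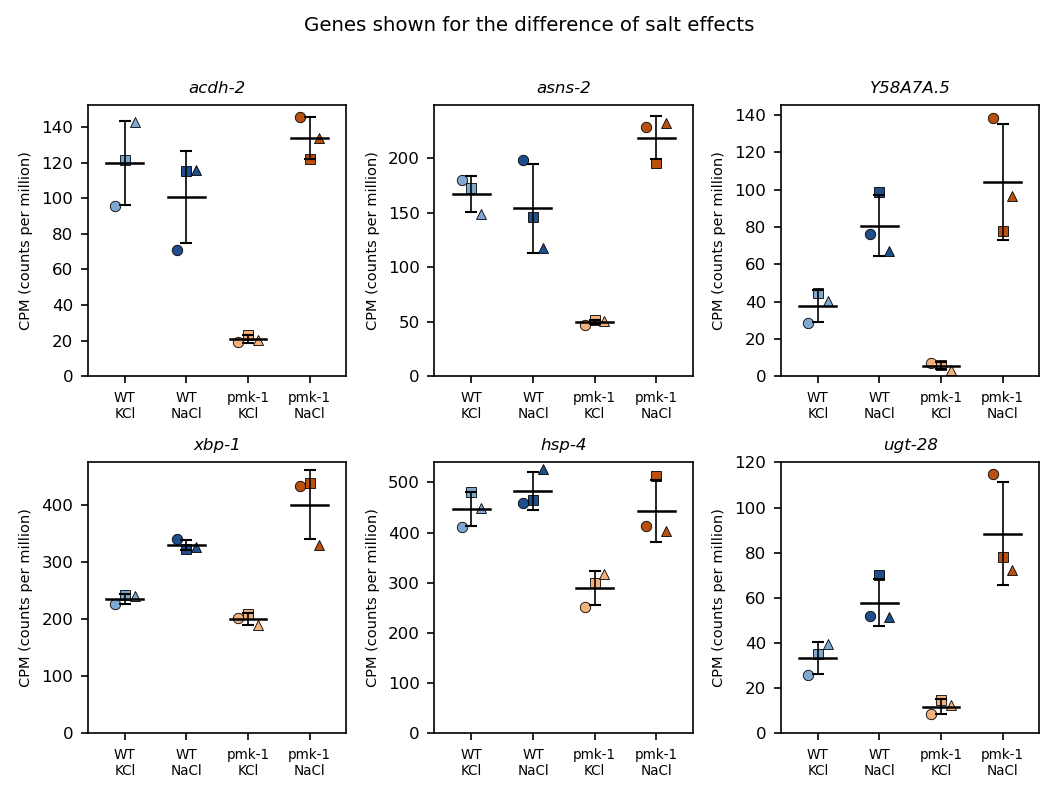
Abundance (CPM, linear axis) of acdh-2, asns-2, Y58A7A.5, xbp-1, hsp-4 and ugt-28 in the 4 groups, n = 3 libraries per group. Symbols are replicates, bars are group means and lines show 1 SD; the first 3 genes passed the edgeR interaction test and the other 3 did not.

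Which genes differed between pmk-1 and wild type in NaCl? Most of the listed immune effector genes were lower in the mutant. C17H12.8, a CUB-like domain gene, stood at 34.2 CPM in wild type and 0.381 CPM in pmk-1 (log2 -6.42 ± 0.53, n = 3 per group), and the lysozyme gene lys-2 at 73.1 and 5.89 CPM (-3.63 ± 0.35), with edgeR quasi-likelihood Benjamini-Hochberg adjusted p = 1.71e-04 and 3.94e-04. Of 10 PMK-1 immune effectors 8 fell, 1 rose (clec-60, log2 3.35) and 1 did not pass in edgeR, with 9 down and 1 up adjusted over the list alone. Their median was -4.67 (-4.21 with the member at 0 in a group at its bound), with a limma camera adjusted p = 8.22e-13 and an adjusted p = 0.00187 with an estimated correlation. Of the epidermal antimicrobial peptides 7 of 11 fell and 4 did not pass in edgeR (7 down adjusted over the list alone), among them nlp-31 (-5.40 ± 0.52, edgeR adjusted p = 3.94e-04) and cnc-4 (-5.12 ± 0.91, 0.00462). Their median was -2.19 (limma camera adjusted p = 8.03e-05; adjusted p = 0.798 with an estimated correlation). Hypodermis and cuticle marker scores were 0.40, 0.35 and 0.04 in wild-type NaCl and 1.44, -0.41 and -0.77 in pmk-1 NaCl. Peptide scores in pmk-1 NaCl had the same order (0.03, -0.77 and -1.47). In wild-type NaCl the peptide scores (1.36, 1.81 and 1.36) did not follow the order of the hypodermis scores. Whether the epidermal RNA content enters the fall was not tested.

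The largest falls included dpy-14, a collagen gene, at 66.0 against 0.683 CPM (log2 -6.55 ± 0.75, edgeR adjusted p = 9.82e-04) and the astacin protease gene hch-1 (-6.21 ± 0.86, 0.00209). fipr-22, raised by NaCl in wild type, fell as well (-5.70 ± 0.41, edgeR adjusted p = 1.15e-04). The largest rises included the Argonaute gene alg-4 (6.41 ± 1.22), the acyl-CoA synthetase gene acs-18 (6.42 ± 1.24) and the tau-tubulin kinase-like gene ttbk-5 (6.38 ± 1.04).

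Sperm markers rose in 52 of 53 genes in edgeR, with 1 not passing (52 adjusted over the list alone; median log2 5.01, or 5.002 with genes at their bound), for example ssp-16 (6.29 ± 1.08, edgeR adjusted p = 0.00417). These markers had a limma camera adjusted p = 1.72e-21 and an adjusted p = 0.798 with an estimated correlation. Of 34 later embryo markers 20 fell and 14 did not pass in edgeR (22 down and 1 up adjusted over the list alone; median -2.81), with the FoxA gene pha-4 at -1.68 ± 0.25 (edgeR adjusted p = 0.00248) and the MyoD gene hlh-1 at -2.65 ± 0.43. Together they had a limma camera adjusted p = 1.05e-11 and an adjusted p = 0.798 with an estimated correlation. Of the collagen genes 44 rose, 4 fell and 53 did not pass in edgeR (58 and 4 adjusted over the list alone, 77 and 5 with the replicate block; median 3.18), and the collagen col-147 rose by 6.72 ± 1.51. Collagens as a list had a limma camera adjusted p = 1.63e-05 and an adjusted p = 0.798 with an estimated correlation. With the embryo covariate their direction reversed to lower (6.95e-08, within 2.51e-16 to 0.798 over the alternatives other than single libraries). Ribosomal protein genes rose in 26 of 78 and 52 did not pass in edgeR (58 adjusted over the list alone, 62 with the replicate block, 10 without the first replicates; median 0.47), in the group with the highest ribosomal RNA share. As a group these had a limma camera adjusted p = 7.50e-10 and an adjusted p = 0.798 with an estimated correlation. With the embryo covariate they did not pass (0.0575, within 5.66e-10 to 0.798 over the alternatives other than single libraries).

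Of the p38 cascade 3 of 14 rose and 11 did not pass in edgeR (2 up adjusted over the list alone; limma camera adjusted p = 0.720): nipi-3 (0.74 ± 0.12, edgeR adjusted p = 0.00343), pmk-3 (0.69 ± 0.20, 0.0258) and kgb-1 (0.58). The call on pmk-3 was lost without wild-type NaCl 1 (0.0515), 2 (0.0640) or 3 (0.111) or pmk-1 NaCl 1 (0.126), and kgb-1 kept its call only without wild-type NaCl 1, pmk-1 KCl 1 or pmk-1 NaCl 3 (edgeR adjusted p from 0.0524 to 0.172 without each of the others). In the sodium pump and cation-chloride list 7 of 26 rose, 2 fell and 17 did not pass in edgeR (9 and 2 adjusted over the list alone; limma camera adjusted p = 0.108), among them the chloride channel gene clh-1 (1.22 ± 0.16, edgeR adjusted p = 0.00175).

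In all, 2232 genes were higher and 1349 lower in pmk-1 in edgeR, 2275 and 2081 without the first replicates. With the later embryo score as a covariate 39 were higher and 92 lower, and with the ribosomal RNA covariate 1772 and 705. In NaCl the embryo scores of the genotypes did not overlap (0.70, 1.15 and 1.03 in wild type, -2.32, -0.99 and -0.96 in pmk-1), nor did the ribosomal RNA shares. Each covariate thus also takes out genotype, and the lower counts cannot tell stage from pmk-1. The replicate block gave 3123 and 2221. The higher count moved to 1076, 1064 and 1192 without wild-type NaCl 2, wild-type NaCl 3 and pmk-1 NaCl 1, and the lower count to 625 and 659 without wild-type NaCl 2 and 3. Sperm and embryo markers differ between the strains in the same libraries, so a gene of this comparison can differ with the stage or brood content of the animals as well as with pmk-1.

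**Figure D5:**
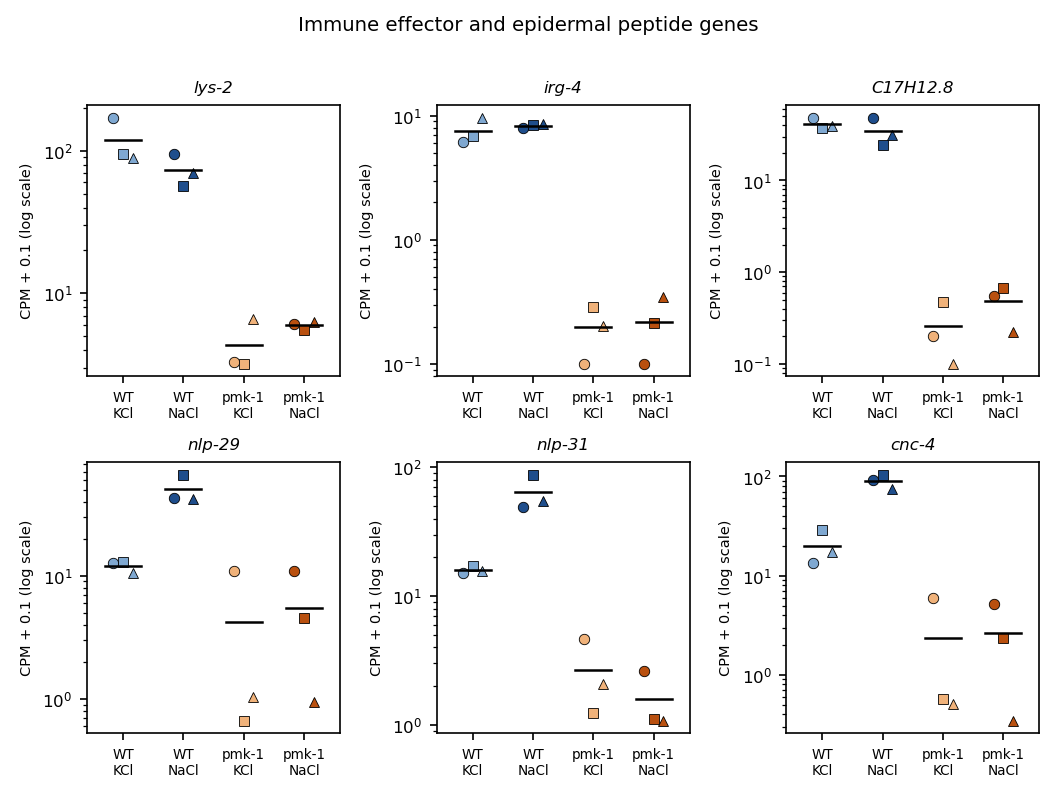
Abundance (CPM plus 0.1, log axis) of lys-2, irg-4, C17H12.8, nlp-29, nlp-31 and cnc-4 in the 4 groups. Symbols are replicates (n = 3 libraries per group) and bars are group means.

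Which genes differed between pmk-1 and wild type in KCl? The immune effectors were again low in the mutant, with 9 of 10 down and 1 up in edgeR over all genes and adjusted over the list alone (median log2 -4.77, or -4.53 with members at 0 in a group at their bound). The effector list had a limma camera adjusted p = 1.50e-15 and an adjusted p = 9.16e-04 with an estimated correlation. C17H12.8 stood at 41.5 CPM in wild type and 0.160 CPM in pmk-1 (-7.86 ± 0.58, n = 3 per group) and lys-2 at 118.1 and 4.28 CPM (-4.79 ± 0.36), with edgeR quasi-likelihood Benjamini-Hochberg adjusted p = 5.46e-05 and 6.45e-05. dod-24, also of the CUB-like family, stood at 26.5 and 0.170 CPM (-7.20 ± 0.33, edgeR adjusted p = 1.31e-06). Of the epidermal antimicrobial peptides 4 fell, 1 rose (nlp-27, log2 1.27) and 6 did not pass in edgeR, with the same counts adjusted over the list alone (limma camera adjusted p = 0.0570), and nlp-31 fell by 2.64 ± 0.46 on the log2 scale. Of 19 hypodermis and cuticle markers 8 fell, 1 rose and 10 did not pass in edgeR. Limma camera placed them lower (adjusted p = 0.0287, 0.783 with an estimated correlation, 0.0659 and 0.122 without pmk-1 KCl 2 and 3). Their scores were 0.5196, 0.078 and 0.0505 in wild-type KCl and 0.04, -0.6364 and -1.0965 in pmk-1 KCl. Peptide scores in pmk-1 KCl had the same order (-0.106, -1.3015 and -1.5949). In wild-type KCl the peptide scores (0.169, 0.397 and 0.1124) did not follow the order of the hypodermis scores. Whether the epidermal RNA content enters these falls was not tested.

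Sperm markers rose in 51 of 53, with 2 not passing, in edgeR (52 adjusted over the list alone; median 5.25, or 5.24 with genes at their bound), such as nspd-2 (5.85 ± 0.90). The sperm list had a limma camera adjusted p = 1.80e-23 and an adjusted p = 0.783 with an estimated correlation. Of 34 later embryo markers 10 fell, 2 rose and 22 did not pass in edgeR (15 down and 2 up adjusted over the list alone; median -1.77), with pha-4 at -2.51 ± 0.25 (edgeR adjusted p = 3.03e-04). For the embryo list limma camera gave an adjusted p = 1.94e-07 and an adjusted p = 0.783 with an estimated correlation. dpy-14 (-7.65 ± 0.76) was again low in pmk-1. Of the collagen genes 22 rose, 5 fell and 74 did not pass in edgeR (22 and 6 adjusted over the list alone; limma camera adjusted p = 8.93e-04; adjusted p = 0.783 with an estimated correlation; 0.182 without pmk-1 KCl 1). The direction of this list reversed with the embryo covariate (7.76e-05).

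This comparison and the pmk-1 salt response share the pmk-1 KCl libraries, so a low value there enters both. Of 18 unfolded protein response genes 10 fell and 8 did not pass in edgeR (11 down adjusted over the list alone; median -0.37), such as pdi-2 (-1.13 ± 0.16, edgeR adjusted p = 0.00172) and pdi-6 (-1.003 ± 0.18). Camera in limma placed them lower at an adjusted p = 2.15e-05 and an adjusted p = 0.783 with an estimated correlation. Of 55 UDP-glucuronosyltransferase genes 9 fell, 1 rose and 45 did not pass in edgeR (8 down and 1 up adjusted over the list alone; limma camera adjusted p = 0.0833), ugt-28 among the falls (-1.50 ± 0.26). catp-3 was lower in pmk-1 (-4.35 ± 0.74, edgeR adjusted p = 0.00383). Potassium channel genes rose in 10 of 49, fell in 1 and did not pass in 38 in edgeR (9 and 1 adjusted over the list alone), for example slo-2 (1.25 ± 0.26, edgeR adjusted p = 0.00704). The channels had a limma camera adjusted p = 0.00324 and an adjusted p = 0.783 with an estimated correlation. They did not pass without the first replicates (0.150) or with the embryo covariate (0.703), within 0.00308 to 0.783 over the alternatives other than single libraries. Of 11 mitochondrial-genome genes 6 rose and 5 did not pass in edgeR (7 up adjusted over the list alone; limma camera adjusted p = 0.00192; adjusted p = 0.783 with an estimated correlation). Of 6 yolk protein genes 4 fell and 2 did not pass in edgeR (4 down adjusted over the list alone; limma camera adjusted p = 0.00379; adjusted p = 0.783 with an estimated correlation; 0.289 with the embryo covariate, within 9.71e-04 to 0.783 over the alternatives other than single libraries), such as vit-5 (-0.98 ± 0.25, edgeR adjusted p = 0.0163; 0.0572 without wild-type KCl 2 and 0.0606 without pmk-1 KCl 1).

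In all, 2031 genes were higher and 1226 lower in pmk-1 in edgeR, and 2653 and 1922 without the first replicates. With the later embryo score as a covariate 740 were higher and 599 lower, and here too a gene can differ with the stage or brood content of the animals as well as with pmk-1. The embryo scores of the genotypes did not overlap in KCl either (0.91, 0.97 and 1.49 in wild type, -2.06, -0.34 and 0.41 in pmk-1). That covariate thus cannot tell stage from pmk-1. The higher count moved to 980, 822 and 1326 without wild-type KCl 2, wild-type KCl 3 and pmk-1 KCl 1, and the lower count to 769 and 568 without wild-type KCl 2 and 3. The genotype effects in NaCl and KCl had a Pearson correlation of 0.91, with 1462 genes higher in both, 808 lower in both and 13 called in opposite directions. They share no library, but same-numbered libraries of a genotype deviated together between the salts, which can raise these values.

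Which genes raised by NaCl in wild type were lower in pmk-1 in NaCl? The overlap of the 23 and the 1349 genes held 11: srr-4, fipr-22, tep-1, ippk-1, C38H2.3, F38B7.2, M117.1, C37A5.3, Y4C6B.2, M03A1.8 and R09E10.13. Both lists use the wild-type NaCl libraries, which raises their overlap without any shared biology. No value without change is at hand to set beside the 11. Of the 11 genes 5 were also lower in pmk-1 in KCl. None of the 11 passed the interaction test (edgeR; M117.1 had the nearest value, -1.34 at an adjusted p = 0.0583). In this fit lower abundance in the mutant was thus called for them and loss of the response to NaCl was not. Over all genes tested, 0 were called less raised in pmk-1 in this fit, 8 with the replicate block, 27 in DESeq2 and 39 without the first replicates. Whether any of the 11 are among those is not given here, so a loss of response stays open. The overlap held 60 genes without the first replicates, 44 in DESeq2, 45 with the replicate block, 24 with the embryo covariate and 4 with the ribosomal RNA covariate. It moved to 3, 0 and 0 without wild-type KCl 1, 2 and 3, 5, 0 and 4 without wild-type NaCl 1, 2 and 3, 22, 7 and 7 without pmk-1 KCl 1, 2 and 3, and 30 and 6 without pmk-1 NaCl 1 and 2.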

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

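The test of the difference of salt effects between the genotypes (edgeR quasi-likelihood interaction, n = 3 libraries per group) was chosen before the data were examined. It found 5 genes more raised by NaCl in pmk-1 than in wild type, by 2.93 (acdh-2), 2.25 (asns-2), 3.09 (Y58A7A.5), 2.64 (Y58A7A.3) and 1.66 (T27D12.1) on the log2 scale. Over the lists, the limma camera test of the same difference passed upwards for the UDP-glucuronosyltransferase family (adjusted p = 7.06e-09), the unfolded protein response (1.38e-06), ribosomal proteins (0.00215), ribosomal RNA (0.00272), the p38 cascade (0.00760) and cytosolic heat shock (0.00806), and downwards for epidermal antimicrobial peptides (4.05e-04), later embryo markers (0.00105) and mitochondrial-genome genes (0.0148). With the correlation estimated from the data none of the 9 passed, at adjusted p from 0.414 to 0.887. The p38 cascade did not pass without the first replicates (adjusted p = 0.155, within 8.72e-04 to 0.414 over its alternatives other than single libraries), nor without wild-type KCl 3 (0.0553), wild-type NaCl 1 (0.0580) or pmk-1 NaCl 1 (0.0801). Of the other 8 lists, all but the UDP-glucuronosyltransferase family and the unfolded protein response also missed the threshold in further alternatives of the limma camera test. With the ribosomal RNA covariate heat shock (adjusted p = 0.205), ribosomal proteins (0.593), antimicrobial peptides (0.333) and mitochondrial-genome genes (0.738) did not pass, and with the embryo covariate ribosomal proteins (0.231) did not. The later embryo and ribosomal RNA lists are left out here under the covariate made from their own values. Ribosomal proteins also did not pass without the first replicates (limma camera adjusted p = 0.533), and mitochondrial-genome genes not with the replicate block (0.0507). Over single libraries left out the limma camera adjusted p ran up to 0.135 (heat shock), 0.673 (ribosomal proteins), 0.115 (antimicrobial peptides), 0.891 (later embryo markers), 0.394 (mitochondrial-genome genes) and 0.0783 (ribosomal RNA).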

How the results depend on the processing

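The alternatives without the first replicates, without ribosomal RNA genes and with a covariate were chosen after the data were seen, and the others before. Genes called numbered 25 (wild-type salt), 362 (pmk-1 salt), 3581 (genotype in NaCl), 3257 (genotype in KCl) and 5 (interaction), with an overlap of 11 and a correlation of salt effects of 0.32, and only values more than 1.5 times away, or a moved correlation, are listed. DESeq2 gave 132, 664 and 108 in the salt comparisons and the interaction, and an overlap of 44. The libraries compared alone gave 154 in wild type, 48 in pmk-1, a correlation of 0.47 and an overlap of 39. The replicate block gave 131, 679 and 40 in the salt comparisons and the interaction and an overlap of 45. In KCl, where the replicate numbers did not pair, it gave 2859 higher and 1959 lower genes. Without the first replicates the same 3 counts were 134, 1070 and 97, with 2081 lower in NaCl and 1922 lower in KCl, a correlation of 0.21 and an overlap of 60. With the later embryo score as a covariate 1.2e+02 were called in wild type (99 higher and 20 lower), 131 in NaCl (39 higher and 92 lower), 1339 in KCl (740 and 599) and 60 in the interaction, and the overlap was 24. With the log2 percent of ribosomal RNA as a covariate the salt comparisons gave 13 and 187 and the interaction 3, with 705 lower in NaCl, a correlation of 0.24 and an overlap of 4. No filter on low counts gave 19 in the interaction and a correlation of 0.11. The stricter filter gave 2125 in NaCl, 1743 in KCl, 2 in the interaction, a correlation of 0.50 and an overlap of 7. A log2 limit of 1 left 853 lower in NaCl and 748 lower in KCl, and a mean of at least 5 CPM gave a correlation of 0.50. With single libraries left out the ranges were 0 to 78 (wild-type salt), 112 to 550 (pmk-1 salt), 1701 to 4327 (NaCl), 1390 to 4473 (KCl), 2 to 20 (interaction), 0 to 30 for the overlap and 0.10 to 0.31 for the correlation. Lists past the threshold numbered 13, 14, 7, 12 and 9 in the same order of comparisons. They numbered 0, 0, 1, 1 and 0 with an estimated correlation, 9 in pmk-1 and 16 in NaCl with the embryo covariate, 12 in NaCl with the ribosomal RNA covariate and 7 in KCl with the block, and 7 to 15, 9 to 18, 7 to 9, 11 to 14 and 6 to 13 with single libraries left out. The embryo covariate reversed the sign in NaCl of grl-21 (-0.89), dim-1 (-0.037), acs-2 (-0.37), mcm-4 (0.069), mcm-5 (0.18), mcm-2 (0.022), ifb-2 (-0.36), cdr-4 (-0.12), hmit-1.1 (-0.49) and aqp-8 (-0.15), and in KCl of eat-6 (-0.55). It also reversed list directions in the limma camera test: collagens in the pmk-1 salt response (adjusted p = 0.0587), collagens (6.95e-08) and oocyte markers (0.158) in NaCl, and collagens (7.76e-05), neuropeptides (0.932) and oocyte markers (0.533) in KCl. The sign of later embryo markers turned as well (limma camera adjusted p = 0.704 in pmk-1 salt, 0.600 in NaCl, 0.698 in KCl and 0.696 in the interaction), but the covariate is their own score, so this tests nothing. The ribosomal RNA covariate reversed ribosomal proteins in the interaction (limma camera adjusted p = 0.593). Sperm markers in wild-type salt reversed without wild-type KCl 3 (0.659) and without wild-type NaCl 1 (4.46e-05), within limma camera adjusted p from 3.25e-17 to 0.659 over the libraries left out. Collagens in pmk-1 salt reversed without pmk-1 NaCl 1 (0.563, the highest of a range from 4.88e-07). Of the named gene results 352 were called alike with median-of-ratios scaling and 6 were not; DESeq2 kept 355, the count table without ribosomal RNA genes 352, the first replicates left out 343, the fit without a filter 344, the ribosomal RNA covariate 296 and the embryo covariate 172. The stricter filter kept 284 and ended 22, the libraries compared alone kept 266 and ended 74, and single libraries left out kept from 274 to 339. The replicate block kept 357 and added 1 call among them, pmk-3 in the pmk-1 salt response, and it ended 7 of 55 list calls, 5 of them in KCl: hypodermis markers (limma camera adjusted p = 0.1095), mitochondrial-genome genes (0.1008), neuropeptides (0.1445), oocyte markers (0.0520) and potassium channels (0.0603). The other 2 were metal response genes in pmk-1 salt (limma camera adjusted p = 0.0576) and mitochondrial-genome genes in the interaction (0.0507). It changed no other call among the named genes and the lists that passed. The cause of these changes was not tested. Embryo scores did not overlap between the genotypes in either salt, so in the genotype comparisons that covariate cannot tell stage from pmk-1. The rounding alternative was not run, as the deposited values are whole numbers. On simulated data 29 to 38 percent of 2-fold changes were called, so a gene not called can still have changed 2-fold.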

Other observations

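The comparisons in this part and all tests of explanations were chosen after results were seen, except for the counts over other splits of the libraries, whose form was set beforehand. Of the 311 genes raised by NaCl in pmk-1, 94 were also called lower than wild type in KCl and 111 called higher than wild type in NaCl, while 4 were higher in KCl and 15 lower in NaCl. Each pair of comparisons shares pmk-1 libraries, which raises the first 2 overlaps without any shared biology, so the counts alone show no pattern. acdh-2 and asns-2 were called lower in the mutant in KCl, with 20.8 and 49.8 CPM in pmk-1 KCl against 119.8 and 167.1 CPM in wild-type KCl, and 133.9 and 218.9 CPM in pmk-1 NaCl against 100.7 and 154.1 CPM in wild-type NaCl. catp-3 was low in every pmk-1 KCl library (13.3, 3.86 and 1.14 CPM against 79.8, 131.6 and 159.0 in wild type) and stayed below wild type in NaCl (234.0, 89.5 and 46.0 against 814.0, 784.0 and 726.0). Of the 51 genes that fell in pmk-1, 26 were higher than wild type in KCl and 16 lower in NaCl.

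Some genes raised by NaCl in pmk-1 lie close to one another. ugt-26 (4721131 to 4723982, log2 2.84 ± 0.39 in pmk-1, edgeR adjusted p = 0.00304), ugt-28 (4727280 to 4730366) and ugt-25 (4731606 to 4735276) lie on the same strand of chromosome I. Y58A7A.3 and Y58A7A.5 lie within 1 stretch of chromosome V (5077854 to 5086969) on the same strand. Genes in the gaps between them were not examined. Reads shared between close relatives were not examined for these genes.

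The first pattern is the broad genotype difference. Across genes, the shift of the first wild-type replicates from the other wild-type libraries had a correlation of 0.716 with the difference of pmk-1 from wild type, and the first pmk-1 replicates one of 0.684, and 2059 of the 2270 genes called in the same direction in both salts (90.7 percent) had the sign of that wild-type shift. The first replicates also enter the difference of pmk-1 from wild type, and no value without a stage difference is at hand for these correlations. A difference in the stage or brood content of the animals may account for much of the genotype difference, and an effect of pmk-1 on stage or brood stays open as well. A difference in depth is argued against by the ratio of mean totals, 0.948. For the PMK-1 immune effectors the median in NaCl was -4.67 before and -4.08 after the embryo covariate (quartiles after it -5.76 and -2.99). Embryo scores did not overlap between the genotypes in NaCl, so this adjustment extrapolates and cannot decide on stage content. The sperm score was not used as a covariate. In the first wild-type replicates the effector median moved by 0.35, the opposite direction to the fall in pmk-1. That argues against stage content as the whole cause but does not exclude it. The splits of 6 libraries into 3 and 3 are 10, too few for a share under 0.05; the real splits gave 3581 genes in NaCl and 3257 in KCl, the highest others 0 and 0, with 1 of 10 as large in each.

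The second pattern is the higher position of epidermal antimicrobial peptides in NaCl in wild type, where 0 of 11 passed over all genes in edgeR (8 at an unadjusted p under 0.05, 3 in DESeq2) and the list had a limma camera adjusted p = 7.24e-11 and an adjusted p = 0.209 with an estimated correlation. More RNA from the epidermis would raise hypodermis and cuticle markers, whose median was -0.155 (quartiles -0.73 and 0.82) beside 0.96 for the peptides (quartiles 0.66 and 2.12). These ranges overlap, and whether the markers follow epidermal RNA in day-1 adults was not tested, so it is not excluded. The peptide median was 0.945 after the embryo covariate and 0.938 after the ribosomal RNA covariate. Later embryo scores overlapped between the salts (0.91, 0.97 and 1.49 in wild-type KCl, 0.70, 1.15 and 1.03 in wild-type NaCl). Ribosomal RNA shares did too, so adjusting could hardly move the median. The sperm score was not used as a covariate, so a stage difference stays open. A response of the epidermis to the medium stays a candidate explanation and was not tested further. The 10 splits of the wild-type libraries are too few for a share under 0.05, with 25 genes in the real split and 0 in the highest other (1 of 10 as large).

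The third pattern is the larger NaCl difference of unfolded protein response and UDP-glucuronosyltransferase genes in pmk-1. Their joint median of 0.466 became 0.551 with the ribosomal RNA covariate (limma camera adjusted p = 3.81e-06 and 1.36e-11). The ribosomal RNA share was at least 3.5244 percent in each pmk-1 NaCl library and at most 3.2581 percent in every other library. That covariate thus nearly marks the pmk-1 NaCl group and cannot decide on the share as a cause. With the embryo covariate the joint median was 0.354 (limma camera adjusted p = 3.78e-07 and 3.99e-07). This argues against the later embryo score as the whole cause. The sperm score was not used as a covariate, so a stage difference stays open. With an estimated correlation and no covariate neither list passed (limma camera adjusted p = 0.414 for both). The epidermal peptides had 0 calls in edgeR over all genes, with 3 down at an unadjusted p under 0.05 and 2 in DESeq2. Their limma camera adjusted p was 4.05e-04, and 0.414 with an estimated correlation. Their median difference went from -1.62 to -0.14 with the ribosomal RNA covariate (quartiles -2.05 and -0.15 before, -0.82 and 0.41 after). As that covariate nearly marks the pmk-1 NaCl group, whether the peptide difference follows the ribosomal RNA share stays open. With the embryo covariate the peptide median was -1.73. The genotype as such stays open and was not tested apart from these. The 10 splits of the pmk-1 libraries are too few for a share under 0.05 (362 genes in the real split, 2 in the highest other, 1 of 10 as large), and for the interaction 7 of 100 drawn splits gave at least its 5 genes. These are the real split and 6 that keep the 3 pmk-1 KCl or the 3 pmk-1 NaCl libraries together and so carry the salt effect of the mutant; the highest, with 344 genes, exchanged the salt labels within one genotype and so points to this structure of the samples. Splits that broke up the mutant salt groups gave at most 2 genes, and whether chance can be excluded stays open.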
